A study of Homo sapiens with 8 samples.

How the data were processed

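Total RNA from the human osteosarcoma cell line MNNG/HOS was hybridised as biotin-labelled cRNA to 8 expression arrays. The labels place 2 arrays in each of 4 groups: DMSO (the solvent control), JQ1, rapamycin, and both drugs together. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns with DNase treatment, checked for quality and labelled with an amplification kit for Illumina arrays. The series' design text names another array maker, but the probe identifiers in both deposited tables are Illumina's. Nothing in the labels says whether the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

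Both deposited tables hold linear probe intensity, one as non-normalized signal and one as the value table attached to the sample records. The non-normalized intensity was deposited with neither detection p-values nor control probes, and 28.3% to 30.3% of its values per array lay below 0, so a background had already been subtracted by the authors. The value table deposited by the authors holds normalized intensity with a floor of 20. Its normalization method, software and any reference build are not given in the sources used here. Each of the 8 columns in that table had a median at the floor, 20, and the log2 scale was taken here from its linear values.

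The columns of the non-normalized table and of the value table were compared by rank correlation over the 14640 probes above the floor on all arrays. Every non-normalized column matched a single column of the value table at 0.997 or more, and no other pair exceeded 0.9795. For 6 of the 8 columns the matching array carried another group or replicate name. The value table, whose columns are tied to the sample records, was therefore used for the results, and the non-normalized signals served as alternatives with their arrays matched to it. This choice was made after rank correlations and principal components of the tables had been seen and before any gene was tested. It departs from the plan, which was to normalize the non-normalized table with limma's neqc. That step, and the planned filter on detection p-values, could not be run without detection p-values or controls. The plan's fallback without detection p-values was no filter at all, and counts without a filter are given with the alternatives.

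Values were log2-transformed. Of 47304 probes, 30102 carried 1 gene symbol in the platform annotation, 8 carried several and 17194 were unnamed here. Symbols of 30063 probes were updated through their gene identifiers to the RefSeq annotation of GRCh38.p14, used for names only. A probe entered if it exceeded 20 on at least 2 of the 8 arrays, which left 23860 probes, 17016 of them with a symbol. The probe with the highest mean log2 value stood for each gene, which gave 12759 genes, 3326 of them with more than 1 such probe. Probes with several symbols or none entered no gene count. Array precision is limited by the 2 arrays per group.

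Differences were tested with limma 3.58.1 in R 4.3.3. One linear model with a mean per group was fitted to all 8 arrays (4 residual degrees of freedom, 2.92 prior degrees of freedom after moderation). Adjusted p-values are Benjamini-Hochberg values within a comparison, and a gene was called when its value was under 0.05. The comparisons were each treatment against DMSO, the combination against each single drug, and the interaction, which is the JQ1 effect with rapamycin minus the JQ1 effect without it. Where every array of a group lay at the floor, the fold is a lower bound computed from the floor itself and is written "at least". The gene lists, the comparisons and most alternative settings were fixed before the data were examined. The table used, the floor filter and the alternatives named as added were not.

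Gene lists, 30 in all, were tested with camera (preset correlation 0.01), adjusted over the lists within a comparison. With a correlation estimated from the data, none of the 51 list calls held, so that each list's call rests on the preset value. The rotation test fry, which asks whether a list's own genes move one way on balance, held for 8 of them. The genes named in the text are, for each treatment against DMSO, the 8 called genes with the largest rise and the 8 with the largest fall whose arrays do not overlap those of the reference group. For the other comparisons the number is 5 each way. Provisional symbols such as those starting with LOC or FLJ were passed over. Up to 4 called members of each called list with the smallest p were added, and BRD2, BRD3, MTOR, RPTOR, FKBP1A, MYC, HEXIM1, SERPINI1, RUNX2, FOSL1, CDKN1A and CCND1 were among the genes always included. Genes named outside this rule are said to have been chosen after their values were seen, except list members quoted as examples with their values.

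Groups share the replicate numbers 1 and 2 in their titles. Deviations from the group means correlated between same-numbered arrays at 0.42 to 0.55 in all 6 pairs of groups, above the limit of 0.1. The numbers were therefore taken to pair the arrays, although the labels name no shared day or batch and only 2 numbers exist. Counts with the replicate number as a block (3 residual degrees of freedom) are given beside the results they move. The procedure was tested on simulated data for JQ1 against DMSO, with 200 of 12759 genes changed in 20 simulations. The model without the block recovered 0.4% of genes changed by 1 on the log2 scale and 44.5% of those changed by 2, with 0.3% false calls. The blocked model recovered 24.6% and 81.7%, with 3.4% false calls. The changed genes were drawn from the brighter genes, so recovery of dim genes was not assessed. Every simulation held the replicate-set shifts fitted to these arrays, so the gain from the block was built in. Alternatives covered the background step, the scaling, the filter, the choice of probe, the variance model, the threshold, the block and the omission of each array in turn. A block for the chip was not run because the tables name no chip. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.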

Results

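Gene expression was measured in MNNG/HOS, an osteosarcoma cell line obtained by chemical transformation of the HOS line, after treatment with JQ1, rapamycin or both. JQ1 is a small molecule that displaces BET bromodomain proteins from acetylated histones, and rapamycin inhibits the kinase complex mTORC1 through the binding protein FKBP1A (FKBP12 in older texts). The series' title asks whether the drugs act in synergy. The labels give 7.5 mM for JQ1 and 12.5 nM for rapamycin; the unit of the JQ1 dose is as labelled and could not be checked. Treatment time is not given in the sources used here. Each of the 4 groups held 2 arrays.

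Mean intensity per array ran from 455.5 to 481.6, and 55.7% to 58.6% of the 47304 probes lay at the floor of 20. Replicates correlated at 0.974 to 0.978 across the 23860 filtered probes. The standard deviation (SD) of a single array within its group, taken over genes from the replicate differences, was 0.38 to 0.42 on the log2 scale. The grouping was then checked on the non-normalized signals with an offset of 50, with the arrays named as in the value table. Only 1 of the 8 arrays correlated best with the other array of its own group. The pairing of arrays into groups ranked 4 of 105 possible pairings by the variance between groups (63.9%, highest 70.5%). Under the array names in the header of the non-normalized table these figures were 0 of 8 arrays, rank 34 and 48%. In the value table, 39.2% of the variance among arrays over 12759 genes lay between arrays with and without JQ1. Replicates 1 and 2 accounted for 24.3%, and arrays with and without rapamycin for 16.5%. Markers of haematopoietic, epithelial, and endothelial, fat, cartilage or muscle cells passed the list test in none of the 6 comparisons, although haematopoietic markers differed between the replicate sets in a comparison chosen after the data had been seen (median 0.44, adjusted p = 0.0461; adjusted p = 0.344 with an estimated correlation).

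The 2 deposited tables named 6 of the 8 arrays differently. The difference was regular. The arrays that the non-normalized table's header called rapamycin-treated were, on all 8 arrays, those of replicate 2 in the value table; its JQ1 arrays were the value table's rapamycin arrays, and its replicate 2 arrays were the value table's JQ1 arrays. All group names below follow the value table, whose columns are tied to the sample records. Should the header be right, every comparison below would be between other groups.

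**Figure D1:**
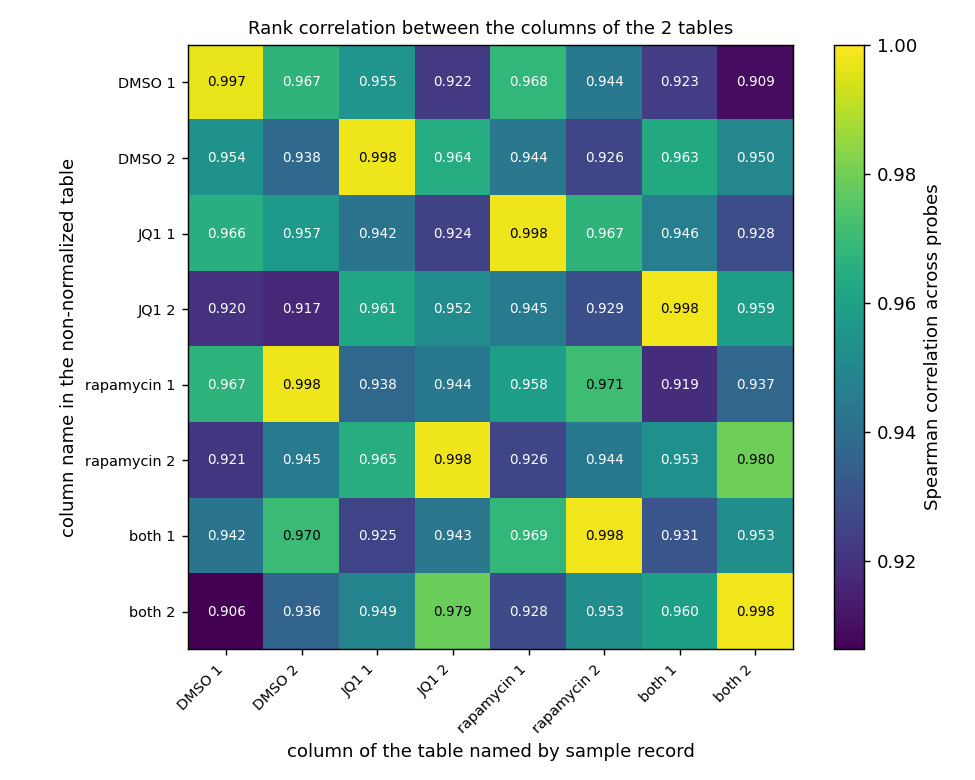
Spearman correlation across 14640 probes between each column of the non-normalized table (rows, by header name) and each column of the value table (columns, by sample record); "both" is JQ1 plus rapamycin. Each row has a single cell at 0.997 or more, and only the first and the last of these lie on the diagonal.

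The first comparison asked what JQ1 alone changed. Genes known to rise after BET inhibition were higher. Among them were the histone genes H2BC5 at 10.1-fold (log2 change 3.34, standard error (SE) 0.52, adjusted p = 0.0267) and H4C14 at 7.33-fold (2.87, SE 0.37, adjusted p = 0.0172). SERPINI1, which encodes the protease inhibitor neuroserpin, rose 7.9-fold (2.98, SE 0.53, adjusted p = 0.0376). Its DMSO arrays stood at 20 and 23.9, so this fold is set partly by the floor. It was called in 0 of the 8 omissions of a single array. A second SERPINI1 probe had a log2 change of 1.37, and the mean of the gene's probes did not pass. H4C15 also rose, by 2.67, but its transcript is nearly identical to that of H4C14, so the 2 values are not independent. All 14 measured members of the list of BET inhibitor response markers were higher, with a median of 2.15. Of these, 4 passed over all genes tested and 12 adjusted over the list alone, and the list was called at adjusted p = 9.54e-10 (adjusted p = 0.438 with an estimated correlation). HEXIM1, a P-TEFb inhibitor often used as a marker of BET inhibition, had a log2 change of 1.97 (SE 0.55, adjusted p = 0.117, or 0.0277 with the replicate block). This change ran from 1.14 to 2.8 over the omissions of a single array.

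Outside that list the largest rises under JQ1 were those of FGFR3, a receptor tyrosine kinase (15.7-fold, log2 3.97, SE 0.36, adjusted p = 0.00891), the transcription cofactor LMO2 (13.0-fold), the AP-1 subunit FOS (12.4-fold), the bHLH factor HES6 (8.59-fold) and METRNL (7.64-fold). For FOS and METRNL 1 DMSO array stood at the floor, so these folds are set partly by it, and neither was called in any of the 8 omissions of a single array. The log2 change of FOS was 2.84 without replicate 1 of DMSO and 4.43 without replicate 2. A second METRNL probe had a log2 change of 0.79, and the mean of the gene's probes did not pass. FGFR3 rested on 1 probe, and its other probe had a log2 change of -0.10. The largest falls were those of RIN2, a regulator of the GTPase Rab5 (log2 -4.09, SE 0.46, adjusted p = 0.0126), the interleukin receptor IL7R (-3.92, SE 0.28, adjusted p = 0.00844), the potassium channel subunit KCNF1 (-3.72), the signalling ligand WNT5A (-3.55, with 1 JQ1 array at the floor) and CCDC9B (-3.54). Falls to the floor were seen for ZMYND8, a reader of chromatin marks (at least 12.9-fold lower), KLHL14 (at least 11.1-fold lower) and the oxysterol-forming enzyme CH25H (at least 8.27-fold lower; log2 -3.67 without replicate 1 of DMSO and -2.42 without replicate 2). RUNX2, the master transcription factor of osteoblasts, was at the floor on both JQ1 arrays (at least 5.17-fold lower, adjusted p = 0.00881), while its second probe had a log2 change of 0.23 and the mean of its probes did not pass. On the non-normalized signals with no further background step RUNX2 had a log2 change of 0.45 (adjusted p = 0.9). The brightest probe per gene was chosen anew on those signals, so this value may come from the second probe.

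Cell-cycle inhibitors and p53 targets rose as a list under JQ1 (median 0.55, adjusted p = 0.000559; adjusted p = 0.555 with an estimated correlation). Of its 23 measured members, 2 rose, or 4 adjusted over the list alone. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, increased 6.33-fold (log2 2.66, SE 0.20, adjusted p = 0.00881) and SESN1 3.7-fold. A second CDKN1A probe, above the floor on 2 arrays, had a log2 change of 0.40, and the mean of the gene's probes did not pass. AP-1 and immediate early genes rose too (median 0.54, adjusted p = 9.39e-05; adjusted p = 0.555 with an estimated correlation). In this list 5 of 32 members rose (11 rose and 1 fell adjusted over the list alone), among them ZFP36 (7.16-fold), EGR1 (3.19-fold) and ETV5 (2.55-fold). Smaller shifts upward passed the test for ER chaperones (median 0.37, 18 of 19 members positive, adjusted p = 0.00104), cholesterol synthesis (0.27, adjusted p = 0.00736) and lysosome genes (0.18, adjusted p = 0.00687). With an estimated correlation their adjusted p were 0.555, 0.718 and 0.708. The cholesterol gene IDI1 alone among these passed singly (2.61-fold, adjusted p = 0.0297). Heat shock and RNA handling genes were also higher (median 0.21, adjusted p = 0.00894; adjusted p = 0.708 with an estimated correlation), with DNAJB4 3.61-fold higher. Mitotic genes fell as a list (median -0.26, 36 of 45 negative, adjusted p = 0.00556; adjusted p = 0.708 with an estimated correlation), and none of them passed singly.

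Among the drug targets, BRD2 rose 2.85-fold under JQ1 (adjusted p = 0.0227). Like SERPINI1, FOS and METRNL, BRD2 lost its call whichever array was left out, as did CH25H, SESN1, EGR1, ETV5, IDI1 and DNAJB4. Over these omissions the log2 change ran from 1.34 to 1.67 for BRD2, 1.6 to 2.17 for SESN1 and 1.35 to 1.99 for EGR1. It ran from 1.17 to 1.54 for ETV5, 1.21 to 1.55 for IDI1 and 1.58 to 2.12 for DNAJB4. The log2 changes of BRD3 (0.25), MTOR (0.38), FKBP1A (0.24), RPTOR (-1.29), FOSL1 (0.11) and CCND1 (-0.34) did not pass. MYC, a gene that BET inhibitors lower in many blood cancers, had a log2 change of 0.97 (SE 0.65, adjusted p = 0.53) and its second probe 1.19. The list of MYC target genes had a median of -0.09 and did not pass (adjusted p = 0.161; adjusted p = 0.84 with an estimated correlation).

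In total, 361 of 12759 genes differed between JQ1 and DMSO (limma), 135 higher and 226 lower, or 196 and 202 when each array was centred on its median. At an unadjusted p under 0.05 there were 2310 genes, against 638 by chance. With the replicate block the count was 1427 (572 higher, 855 lower) and included all 361; on the non-normalized signals it ran from 101 to 648, and without a filter it was 145. By limma no gene was called without any single DMSO or JQ1 array, or when only these 4 arrays were fitted; without a rapamycin array the count was 125, without a combination array 163, and at an adjusted p under 0.01 it was 28. Without replicate 1 of DMSO or replicate 2 of JQ1 the mitotic, cholesterol and lysosome lists were no longer called, and without replicate 2 of DMSO or replicate 1 of JQ1 the heat shock list was not.

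**Figure D2:**
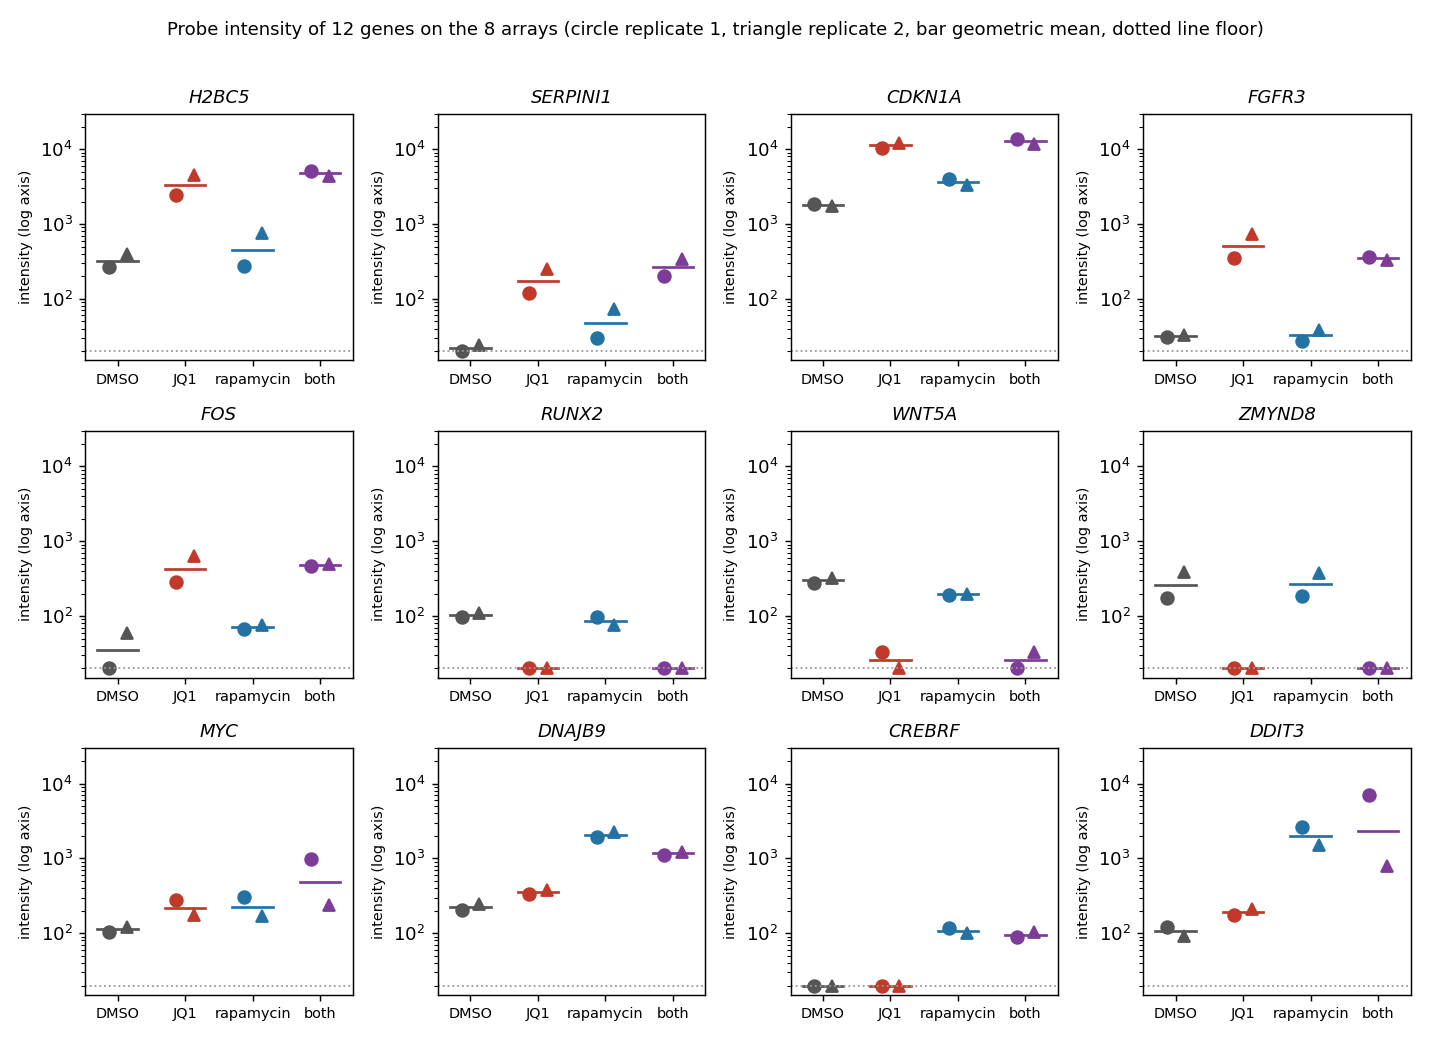
Intensity on a log axis for 12 genes, with replicate 1 as a circle, replicate 2 as a triangle, the geometric mean of the 2 arrays as a bar and the floor of 20 as a dotted line; "both" is JQ1 plus rapamycin. H2BC5, SERPINI1, CDKN1A and FGFR3 stood higher and RUNX2 and ZMYND8 stood at 20 in both groups given JQ1, while DNAJB9 and CREBRF stood higher in both groups given rapamycin; MYC and DDIT3 differed most between the 2 combination arrays.

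The second comparison asked what rapamycin alone changed. DNAJB9, which encodes an ER-resident co-chaperone induced by unfolded proteins, rose 9.32-fold (log2 3.22, SE 0.20, adjusted p = 0.00607). CREBRF, a regulator of CREB3 that is itself linked to ER stress, was at the floor in DMSO and rose at least 5.37-fold (adjusted p = 0.0199). It was no longer called with a trended robust variance or on the non-normalized signals with no further background step. Its call was also lost whichever array was left out, with a log2 change, computed from the floor, of 2.31 to 2.54. KLHL14 fell to the floor (at least 11.1-fold, adjusted p = 0.00607), while its second probe, above the floor on 1 array, had a log2 change of -0.01 in every treatment. No other gene passed. DNAJB9, CREBRF and KLHL14 remained among the 44 genes (30 higher, 14 lower) called with the replicate block. Examples from those 44, chosen after their values were seen, were GDF15 (log2 3.80), FICD (2.32), PPP1R15A (2.03) and XBP1 (1.87), all tied to ER or integrated stress responses. Lower in that fit were the BMP targets SMAD6 (-1.93) and ID3 (-1.47), the WNT target AXIN2 (-1.77) and the phosphatase CDC25A (-1.64).

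Gene lists shifted where single genes mostly did not. All 19 measured ER chaperone and unfolded protein response genes were higher with rapamycin (median 0.59, adjusted p = 8.5e-12; adjusted p = 0.0996 with an estimated correlation). Of these, 1 passed over all genes and 7 adjusted over the list alone. Targets of ATF4, the transcription factor of the integrated stress response, rose as a list of 33 (median 0.77, 27 positive, adjusted p = 7.94e-09; adjusted p = 0.372 with an estimated correlation). None of its members passed over all genes and 8 did adjusted over the list alone; DDIT3 had a log2 change of 4.24, TRIB3 of 3.37, CTH of 3.16 and CHAC1 of 2.78. Lists of lysosome and autophagy genes (median 0.29, adjusted p = 8.43e-06), cholesterol synthesis (0.42, adjusted p = 2.04e-05) and p53 targets (0.42, adjusted p = 2.23e-05) rose. With an estimated correlation their adjusted p were 0.372, 0.449 and 0.372. AP-1 genes (median 0.40, adjusted p = 3.41e-05), NF-kB targets (0.32, adjusted p = 0.00215) and BET response markers (0.49, adjusted p = 0.0267) rose as well, and their adjusted p with an estimated correlation were 0.434, 0.212 and 0.466.

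Lower with rapamycin were lists of G1/S and DNA replication genes (median -0.33, 9 of 48 positive, adjusted p = 2.1e-06), MYC targets of the nucleolus and metabolism (-0.28, 6 of 37 positive, adjusted p = 0.000644) and osteoblast lineage genes (-0.49, 4 of 23 positive, adjusted p = 5.82e-06). With an estimated correlation their adjusted p were 0.543, 0.653 and 0.0996. Osteoblast genes were lower for 5 members adjusted over the list alone. Log2 changes in this list were -1.28 for CDH11, -1.06 for ID2 and -0.95 for COL1A1, the main collagen of bone, and -0.28 for RUNX2. Heat shock and RNA handling genes had a median of 0.03 and did not pass (adjusted p = 0.572; adjusted p = 0.83 with an estimated correlation). MTOR (log2 0.05), RPTOR (-0.78), FKBP1A (0.04), MYC (1.01), CCND1 (-1), CDKN1A (1.04), SERPINI1 (1.10), BRD2 (0.46), BRD3 (-0.41) and FOSL1 (0.31) did not pass either. HEXIM1 was at the floor with rapamycin and did not pass.

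The count of called genes was 3 (2 higher, 1 lower; 8 and 1 with median centring), with 1262 genes at an unadjusted p under 0.05 against 638 by chance. The count was 0 without any single DMSO, JQ1 or rapamycin array and with only the 4 arrays compared, 20 with an offset of 50 on the non-normalized signals, 15 without a filter and 1 over probes above the floor on all arrays. Without replicate 1 of DMSO or replicate 2 of rapamycin the lists of MYC targets (adjusted p = 0.239 and 0.302) and BET response markers (0.253 and 0.184) were no longer called; BET response markers were also lost on the non-normalized signals with an offset of 50 (adjusted p = 0.0586).

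The combination was then compared with DMSO. TXNIP, a glucose-responsive inhibitor of thioredoxin, had the largest rise (37.2-fold, log2 5.22, SE 1.20, adjusted p = 0.0484). DDIT3, the stress transcription factor CHOP (22.2-fold, log2 4.47, SE 0.90, adjusted p = 0.035), ATF3 (14.5-fold), LMO2 (14.3-fold), FOS (13.9-fold) and the metallothionein MT1H (12.3-fold) followed. DDIT3 stood at 7055.3 and 781.9 on the 2 combination arrays, so its size rests heavily on replicate 1, as does that of ATF3 (1273.3 and 200.6). ATF3 had a log2 change of 2.52 without replicate 1 of the combination and 5.19 without replicate 2, and DDIT3 of 2.89 and 6.06. Each was called in 1 of the 8 omissions of a single array. TXNIP stood at 1527.5 and 8740.4, with a log2 change of 6.48 and 3.96 without these arrays in turn, and was not called with array weights. LMO2 ran from 3.16 to 4.51 in the same way. Without replicate 1 or 2 of DMSO, FOS, with 1 DMSO array at the floor, had 3 and 4.59 and MT1H 3.01 and 4.24. Histone genes H2BC5 (14.6-fold) and H4C14 (14.1-fold) rose again. The largest falls were those of KCNF1 (log2 -3.98, SE 0.31, adjusted p = 0.00403), the acetylcholine receptor subunit CHRNA9 (-3.86), TNFRSF11B, which encodes the decoy receptor osteoprotegerin (-3.69), CCDC102A (-3.64), WNT5A (-3.54) and BCL3 (-3.51). CCDC102A and WNT5A each had 1 combination array at the floor, so their falls are set partly by it. Without replicate 1 or 2 of the combination BCL3 had -2.64 and -4.39, and CHRNA9 -3.24 and -4.47. BCL3 was called in 1 of the 8 omissions. ZMYND8 (at least 12.9-fold), CDCP1 (at least 12.8-fold) and RUNX2 (at least 5.17-fold, adjusted p = 0.00403) fell to the floor. Of 23 osteoblast lineage genes 5 fell, with 6 lower and 1 higher adjusted over the list alone, and the list was not called (median -0.10, adjusted p = 0.218; adjusted p = 0.421 with an estimated correlation).

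Of the 14 BET response markers, 10 rose with the combination (median 3.05, adjusted p = 4.22e-11; adjusted p = 0.259 with an estimated correlation), and 12 adjusted over the list alone. H4C8, at the floor in DMSO, rose at least 8.9-fold (log2 2.49 without replicate 1 of the combination and 3.82 without replicate 2). Of 32 AP-1 and immediate early genes 16 rose (17 rose and 1 fell adjusted over the list alone), with DUSP1 5.36-fold, EGR1 4.53-fold, ETV5 3.8-fold and KLF6 3.48-fold higher (median 0.83, adjusted p = 2.71e-07; adjusted p = 0.421 with an estimated correlation). Of 23 cell-cycle inhibitors and p53 targets 8 rose (14 adjusted over the list alone; median 1, adjusted p = 1.1e-08; adjusted p = 0.259 with an estimated correlation). Here CDKN1A rose 7.12-fold, CDKN2D 4.13-fold, the BCL2 family member PMAIP1 3.34-fold (not called with the mean of its probes) and TP53INP1 2.15-fold. Lysosome and autophagy genes rose in 7 of 42 cases (9 rose and 1 fell adjusted over the list alone), with MAP1LC3B 4.06-fold, NEU1 2.89-fold, RRAGC 2.72-fold and NPC1 2.27-fold higher (median 0.26, adjusted p = 0.000326; adjusted p = 0.421 with an estimated correlation). The sterol regulator INSIG1 (7.26-fold) and IDI1 (4.11-fold) were the 2 cholesterol genes of 19 that rose (2 adjusted over the list alone; median 0.54, adjusted p = 1.77e-05; adjusted p = 0.421 with an estimated correlation). DNAJB9 (5.22-fold) and the ubiquitin ligase SYVN1 (2.27-fold) were the 2 ER chaperone genes of 19 that rose (5 adjusted over the list alone; median 0.57, adjusted p = 1.01e-05; adjusted p = 0.259 with an estimated correlation). Ribosomal protein genes shifted by a median of 0.13 (adjusted p = 0.0119; adjusted p = 0.535 with an estimated correlation); this call was lost on the non-normalized signals (adjusted p = 0.242 and 0.205) and without replicate 1 of the combination (0.219).

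Lists of G1/S genes, mitotic genes and MYC targets were called lower with the combination. The 4 of 48 G1/S genes that fell were E2F2 (log2 -2.61, SE 0.28, adjusted p = 0.00726), CHAF1A (-1.34), GINS3 (-1.33) and MCM3 (-1.25), with 7 adjusted over the list alone (median -0.47, adjusted p = 0.000313; adjusted p = 0.584 with an estimated correlation). The 3 of 45 mitotic genes were AURKA (-1.85), BUB1B (-1.51) and PLK1 (-1.06, not called with array weights), with 2 adjusted over the list alone (median -0.37, adjusted p = 0.00082; adjusted p = 0.421 with an estimated correlation). The 3 of 37 MYC targets were the folate carrier SLC19A1 (-1.86), PPRC1 (-1.68) and PPAN (-1.58), with 5 adjusted over the list alone (median -0.49, adjusted p = 0.000193; adjusted p = 0.584 with an estimated correlation). This last list was not called without replicate 2 of the combination (adjusted p = 0.122). CHAF1A, GINS3, MCM3 and PLK1 were not called with median centring, with no further background step on the non-normalized signals or without a filter. CHAF1A was also lost with an offset of 50 or 16, and MCM3 with 16. CHAF1A, GINS3, PLK1, PPRC1 and, among the rises above, CDKN2D lost their calls whichever array was left out. Over these omissions the log2 change ran from -1.57 to -1.12 for CHAF1A, -1.52 to -1.14 for GINS3 and -1.26 to -0.86 for PLK1. MYC itself had a log2 change of 2.09 (SE 0.65, adjusted p = 0.105, or 0.0231 with the replicate block), and its second probe 2.42. It stood at 976 and 235 on the 2 combination arrays, and its log2 change ran from 1.07 to 3.12 over the omissions of a single array. SERPINI1, with 1 DMSO array at the floor, rose 12.2-fold and BRD2 2.61-fold. HEXIM1 (log2 1.11), MTOR (0.22), FKBP1A (0.33), BRD3 (0.02) and FOSL1 (-0.17) did not pass. RPTOR, at the floor with the combination (adjusted p = 0.132), and CCND1 (-0.82, adjusted p = 0.187) did not pass either. With the replicate block their adjusted p were 0.0461 and 0.0455. Both also passed with an offset of 16 on the non-normalized signals, and CCND1 with an offset of 50.

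The combination differed from DMSO in 916 genes, 374 higher and 542 lower (473 and 439 with median centring), with 3019 at an unadjusted p under 0.05. With the replicate block the count was 2416 (991 higher, 1425 lower) and included all 916. On the non-normalized signals it was 497 with no further background step, 1324 with an offset of 50 and 1176 with an offset of 16. Without a filter it was 236, at an adjusted p under 0.01 it was 117, and with only the 4 arrays compared it was 0. Without replicate 1 or 2 of DMSO the count was 47 or 61, without replicate 1 or 2 of the combination 0 or 318, without a JQ1 array 555 and without a rapamycin array 372.

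**Figure D3:**
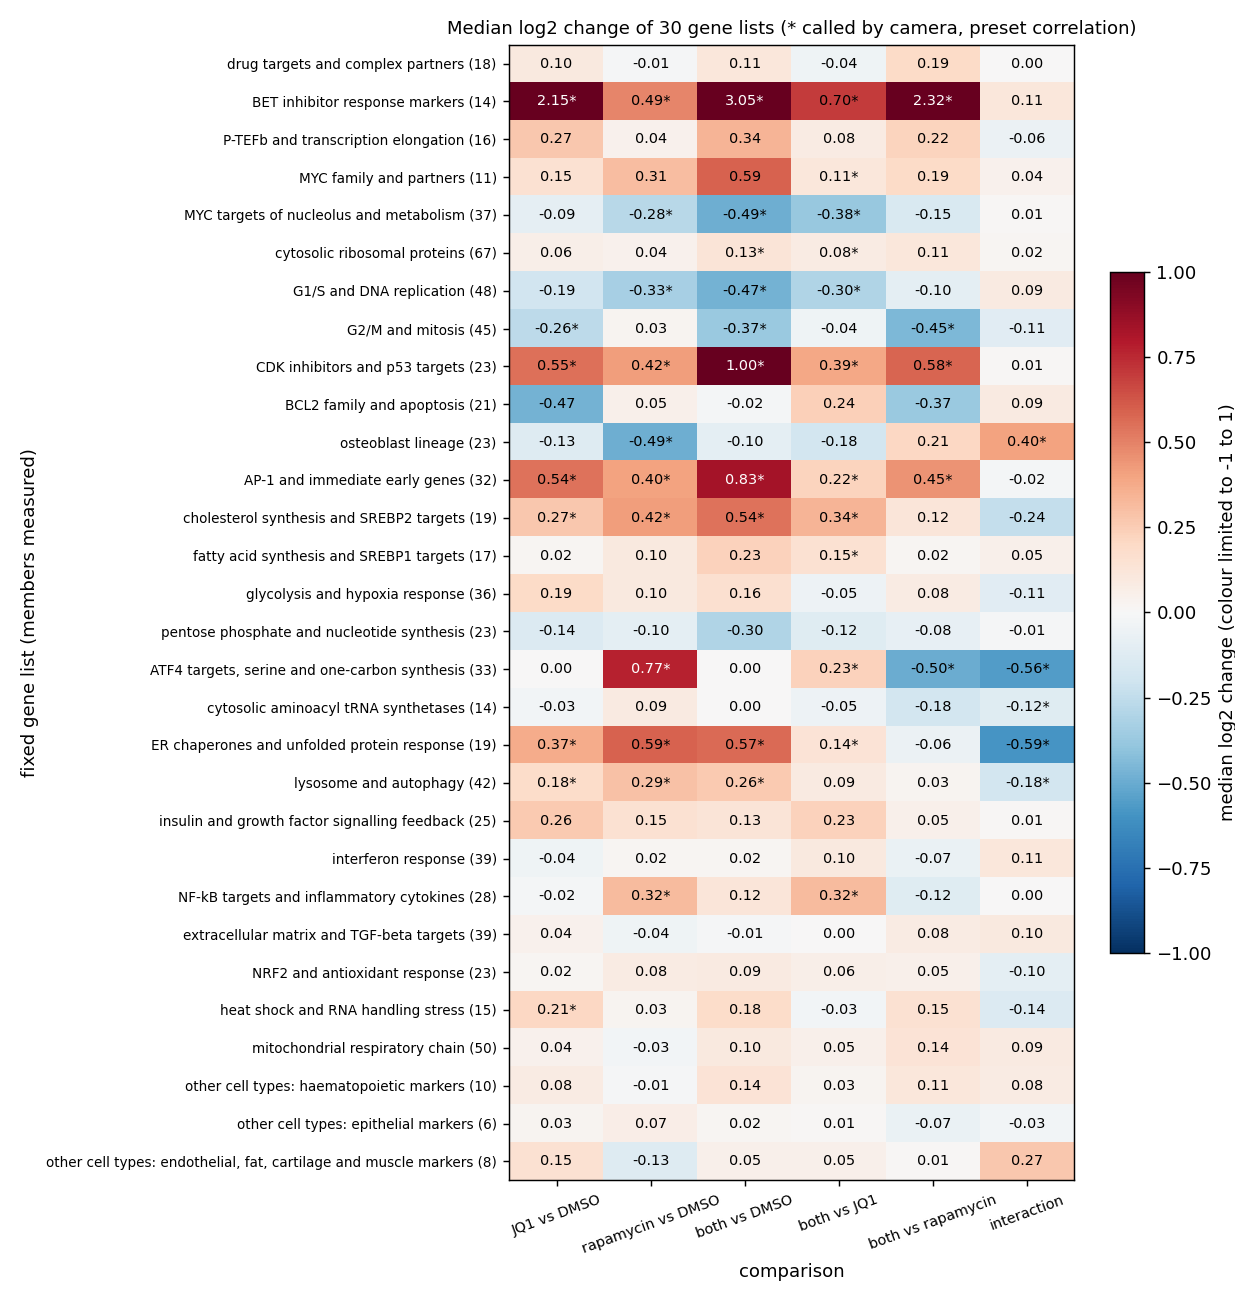
Median log2 change over the measured members of the 30 fixed gene lists (rows, with the number measured) in the 6 comparisons (columns); "both" is JQ1 plus rapamycin, red is higher, blue is lower, colours stop at 1 and -1, and an asterisk marks lists called by camera with the preset correlation. BET response markers had medians of 2.15, 3.05 and 2.32 where JQ1 was added, while ATF4 targets stood at 0.77 with rapamycin alone.

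Next, the combination was set against each single drug. Against rapamycin, which isolates what JQ1 added, 334 genes differed, 120 higher and 214 lower (147 and 162 with median centring). The poly(A) polymerase TENT5C (12.2-fold, adjusted p = 0.0454), the ephrin ligand EFNB2 (11.3-fold, adjusted p = 0.0135), FGFR3 (10.7-fold), H2BC5 (10.5-fold) and H4C14 (10-fold) rose most. TENT5C had a log2 change of 2.84 and 4.38 without replicate 1 or 2 of rapamycin, and lay within that range without either combination array. It was called in 0 of the 8 omissions and not with array weights. H2BC5 had 2.65 and 4.13 without replicate 1 or 2 of rapamycin. CHRNA9 (log2 -4.27, SE 0.43, adjusted p = 0.0144), ZMYND8 (at least 13.2-fold lower), the homeobox gene IRX4 (-3.11), IL1RAPL1 (-2.98) and KCNF1 (-2.92) fell most. Without replicate 1 or 2 of the combination CHRNA9 had -3.66 and -4.89, and IL1RAPL1 -2.37 and -3.60. RUNX2 was at least 4.25-fold lower (adjusted p = 0.0144) and CDKN1A 3.47-fold higher (not called with the mean of its probes). SERPINI1 had a log2 change of 2.50 (adjusted p = 0.0602; 0.00478 with the replicate block) and BRD2 of 0.92 (0.0786; 0.0243 with the block). Of 14 BET response markers 4 rose and 13 did adjusted over the list alone (median 2.32, adjusted p = 1.37e-11; adjusted p = 0.326 with an estimated correlation). Mitotic genes fell (median -0.45, adjusted p = 0.000146), with KIF14 (-1.43) and AURKA (-1.52) the 2 of 45 called (4 adjusted over the list alone; neither was called with array weights). AP-1 genes rose (0.45, adjusted p = 0.000146), with IER5 (3.07-fold) the 1 of 32 members called (8 adjusted over the list alone). P53 targets rose too (0.58, adjusted p = 0.000146), with CDKN1A the 1 of 23 called (5 adjusted over the list alone). With an estimated correlation these 3 lists had an adjusted p = 0.63. Like TENT5C, the genes H2BC5, H4C14, IL1RAPL1, KIF14, AURKA and IER5 lost their calls in this comparison whichever array was left out. Over these omissions the log2 change ran from 2.77 to 3.88 for H4C14 and 1.49 to 1.74 for IER5. It ran from -1.65 to -1.21 for KIF14 and -1.74 to -1.29 for AURKA, and neither was called with median centring. ATF4 targets fell as a list, with 0 of 33 called (5 adjusted over the list alone; median -0.50, adjusted p = 0.000413; adjusted p = 0.654 with an estimated correlation), but not without replicate 2 of the combination (-0.31, adjusted p = 0.45).

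The replicate block raised the count against rapamycin from 334 to 1445 (545 higher, 900 lower), and 2339 genes had an unadjusted p under 0.05. It was 92 on the non-normalized signals with no further background step, 656 and 587 with an offset of 50 and 16, 107 without a filter and 0 at an adjusted p under 0.01 or with only the 4 arrays compared. Without any single rapamycin or combination array it was 0, without a DMSO array 73 and without a JQ1 array 46.

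Against JQ1, which isolates what rapamycin added, limma called 0 genes, with 1057 at an unadjusted p under 0.05 against 638 by chance. With the replicate block it called 2, FBXO32, an atrophy-related ubiquitin ligase (log2 2.62, adjusted p = 0.0354), and CREBRF (at the floor in JQ1, adjusted p = 0.0354). Without a filter 12 genes were called. Of the fixed lists, 12 were called. G1/S genes (median -0.30, adjusted p = 0.000464) and MYC targets (-0.38, adjusted p = 0.000464) fell. BET response markers (0.70, adjusted p = 0.000495), p53 targets (0.39, adjusted p = 0.000342), AP-1 genes (0.22, adjusted p = 0.000464) and NF-kB targets (0.32, adjusted p = 0.000582) rose. With an estimated correlation the adjusted p of these 6 lists were 0.623, 0.623, 0.426, 0.426, 0.554 and 0.413. Without replicate 1 of JQ1 the G1/S (adjusted p = 0.632), MYC target (0.715) and BET marker (0.132) calls were lost, and without replicate 2 of the combination the first 2 were (0.276 and 0.681). The remaining 6 called lists had medians of 0.08 to 0.34. They were cholesterol synthesis, ER chaperones, MYC family, ribosomal proteins, fatty acid synthesis and ATF4 targets. Their adjusted p were 0.00211, 0.0138, 0.0264, 0.0264, 0.0294 and 0.0301, and adjusted p = 0.623, 0.437, 0.426, 0.623, 0.426 and 0.623 with an estimated correlation. The MYC family (adjusted p = 0.0672) and ATF4 targets (0.0504) were not called with the replicate block. Each of those 6 lost its call without replicate 1 of the combination.

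The drugs' effects were then set beside each other. The JQ1 effect without rapamycin and the JQ1 effect with it share no array. Across genes, which are not independent replicates, they correlated at r = 0.75. Both called 193 genes, all in the same direction, against 1.3 higher and 3.8 lower for independent lists. The 2 comparisons used the same spread per gene from 1 fit, so their calls are not independent and these numbers are only a rough reference. The rapamycin effects without and with JQ1 correlated at r = 0.49. JQ1 and the combination, both against DMSO, shared 308 called genes in the same direction (114 higher, 194 lower), or 1143 with the replicate block. Independent lists would share 4.0 higher and 9.6 lower. In 100 simulations of unchanged groups against the same controls the mean overlap was 0. Unchanged groups hold almost no called genes, so that 0 was fixed in advance and is no reference for the 308. The changes of JQ1 and the combination correlated at r = 0.83. The simulated r was 0.50, which a shared control of equal size gives any 2 unchanged groups. Their covariance was 0.36 (simulated 0.072, or 0.034 with the replicate sets kept, a simulation chosen after the data had been seen). All 3 genes called with rapamycin were called with the combination (33 with the block, and 1 in the opposite direction), with a covariance of 0.176 (0.035 with the replicate sets kept). JQ1 and rapamycin shared only KLHL14 (10 genes with the block, and 1 in the opposite direction). Their changes correlated at r = 0.32, for which the simulated 0.50 is no reference because it holds for unchanged groups only. Their covariance was 0.087. Shared controls alone gave this pair 0.072 with independent arrays and 0.034 with the replicate sets kept (highest of 100 simulations 0.038). The 2 DMSO arrays were not split between the comparisons, so part of each overlap may come from the shared controls.

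**Figure D4:**
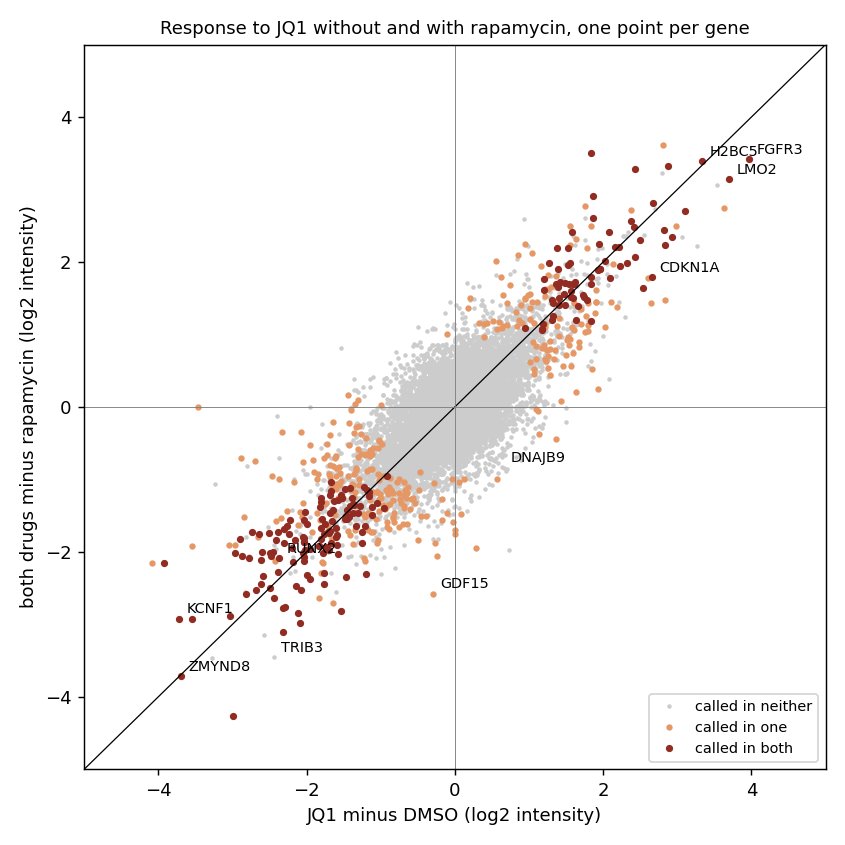
Each point is a gene, with its log2 change from DMSO to JQ1 on the horizontal axis and from rapamycin to the combination on the vertical axis; the black line marks equal changes. The 193 genes called in both comparisons changed in the same direction in both, while DNAJB9 and GDF15 lie below the line.

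The interaction tested whether the 2 drugs together departed from the sum of their log2 changes. With limma, 0 of 12759 genes passed, and 448 had an unadjusted p under 0.05 against 638 by chance, or 930 with the replicate block. The median 95% interval reached 0.92 on either side for a single gene, before adjustment over all genes, so larger departures would often have gone undetected too. The JQ1 comparison had a smaller median SE (0.28 against 0.39). In its simulation the same model recovered 0.4% of changes of 1 and 44.5% of changes of 2. A count of 0 therefore says little about additivity. With the replicate block the single call was KLHL14 (adjusted p = 0.0372), which stood at the floor in all 3 treated groups, so its interaction has no measured size. Without a filter 18 genes passed.

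With the preset correlation, camera called 5 lists for the interaction, and none of them passed with an estimated correlation. ER chaperone and unfolded protein response genes had a median interaction of -0.59 (2 of 19 positive, adjusted p = 2.56e-07; adjusted p = 0.225 with an estimated correlation), with PDIA4 at -1.01, XBP1 at -0.94 and DNAJB9 at -1.50. ATF4 targets had -0.56 (6 of 33 positive, adjusted p = 0.000189; adjusted p = 0.949 with an estimated correlation), which became -0.10 without replicate 2 of the combination (adjusted p = 0.604). Osteoblast lineage genes had 0.40 (18 of 23 positive, adjusted p = 0.000946; adjusted p = 0.225 with an estimated correlation), and the call was lost without replicate 2 of JQ1 (adjusted p = 0.1). Lysosome genes (-0.18, adjusted p = 0.0294) and aminoacyl tRNA synthetases (-0.12, adjusted p = 0.0306) passed narrowly, with an adjusted p = 0.949 for both with an estimated correlation, and each lost its call without any of 4 arrays.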

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

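Of the tests in this part, only the JQ1 comparison under the header's names was set before its result was seen; all others were chosen afterwards, and the allowances for spread in their bounds were also set after the values were known.

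Gene lists whose response to one drug differed with the other, by the interaction test with the preset correlation, were ER chaperones and unfolded protein response (median -0.59), ATF4 targets (-0.56), osteoblast lineage (0.40), lysosome and autophagy (-0.18) and aminoacyl tRNA synthetases (-0.12). None of the 5 passed with an estimated correlation (adjusted p = 0.225, 0.949, 0.225, 0.949 and 0.949). RIN2 and DNAJB9 stood out among the named genes because each array moved by more than 0.5 one way without the other drug and the opposite way with it. The rapamycin effect on RIN2 was -0.89 against DMSO and 1.04 against JQ1, a difference of 1.93 (SE 0.65; adjusted p = 0.999, 0.313 with the replicate block). The JQ1 effect on DNAJB9 was 0.66 without rapamycin and -0.84 with it, a difference of -1.5 (adjusted p = 0.999, 0.386 with the block). Probes without a gene symbol, which enter no gene count, also differed. Of 6844 such probes tested, 57 were called in JQ1 against DMSO (21 higher), 140 in the combination against DMSO (69 higher) and 53 in the combination against rapamycin (20 higher).

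The deposited tables name 6 of the 8 arrays differently, and at least 1 of the namings must be in the wrong order. Both namings were tried on the non-normalized signals with an offset of 50. With the header's names the BET response list had a median of 0.80 in JQ1 against DMSO (12 of 14 members higher), which fell between the bounds set and decided nothing. With the names of the sample records it was 1.5 on these signals (14 of 14 higher), as needed if those are right, and 2.15 on the value table. Over all 8 arrays, this list differed by 1.59 between the header's replicates 2 and 1 (14 of 14 higher, SD 0.77) and by 0.55 between its JQ1 and other arrays. This argues against the header, under which replicate number would move BET response genes more than JQ1. Which remaining axis is rapamycin and which is replicate number is not decided by this list, and stays open. On the same signals ATF4 targets had medians of 0.43 on the records' rapamycin axis and -0.16 on their replicate axis. Unfolded protein response genes had 0.32 and -0.01, and glycolysis and hypoxia genes -0.01 and 1. No outcome was set in advance for these lists, so they do not decide it either. Neither deposited table gives a naming that keeps the sample records' JQ1 arrays and swaps only these axes. Take the header's names group by group: DMSO, JQ1, rapamycin, both, with replicates 1 and 2 in turn. Their matches ran through the records' 4 groups of replicate 1 and then the 4 groups of replicate 2, in the same group order.

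Unfolded protein response genes were higher with rapamycin. The rise was present in both replicate sets, which argues against a shift of 1 set alone. The median was 0.63 in set 1 and 0.65 in set 2, with 18 of 19 members higher in both. The SE of 0.17 is over the list's genes, which are not independent. It leaves out the spread between arrays, since each set held 1 array per group. General stress of culture or RNA handling cannot be told apart from a drug effect, because the heat shock list had a median of 0.03 but its 15 members spread with an SD of 0.55. A response to rapamycin itself, which the design names, stays open and may be the source, subject to the naming of the arrays.

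For RUNX2 and FGFR3, 2 probes disagreed under JQ1. For FGFR3, the first probe averaged 32.3 in DMSO and reached 351 and 732 with JQ1, while the second averaged 66.5 in DMSO and 66.2 with JQ1 (SD 33). The second probe lay above the floor of 20 on all 8 arrays, so the floor set none of its values and cannot have hidden a rise. The bounds set for its level with JQ1 decided nothing, because its 2 JQ1 arrays spread too widely. Why it did not rise stays open. For RUNX2, the second probe averaged 36.3 in DMSO (52.7 and 20, SD 23.1) and stood at 39.3 and 37 with JQ1, so nearness to the floor cannot be told apart from other reasons, because its 2 DMSO arrays spread too widely. Different transcripts were not tested for either gene.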

How the results depend on the processing

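Of the alternatives in this part, 16 in place of 50 as the offset, the header's own array names, the estimated correlation with the block, and the list tests on signals with an offset of 50 were chosen only after the data had been seen. Of 92 values of called genes, 91 kept their direction in every alternative run. Of their 1820 values under alternatives, 1101 were still called. The cause was not tested for any shift below except where the setting itself leaves fewer arrays or probes or a stricter threshold. With 55.7% to 58.6% of probes at the floor, signal over background limits changes of dim genes. The planned neqc normalization, the detection filter and the chip block were not run.

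With only the 4 arrays compared, limma called 0 genes for JQ1, rapamycin and the combination against DMSO and 0 for the combination against rapamycin (2279, 1430, 2677 and 2153 at an unadjusted p under 0.05). With the replicate block the counts were 1427, 44, 2416, 2 (against JQ1), 1445 (against rapamycin) and 1 (interaction), and the overlaps were 1143 for JQ1 with the combination, 33 for rapamycin with the combination and 10 for JQ1 with rapamycin. On the non-normalized signals with no further background step, JQ1 gave 101, the combination 497, the combination against rapamycin 92 and the interaction 1, with overlaps of 86 and, for JQ1 with rapamycin, 2. With an offset of 50 the counts were 648 for JQ1, 20 for rapamycin and 1324 for the combination. The combination against rapamycin gave 656, and the overlaps were 544, 15 and 3. With an offset of 16 rapamycin gave 7, the combination 1176, the combination against rapamycin 587 and the interaction 1. The overlap for rapamycin with the combination was 6. Without a filter the 6 counts were 145, 15, 236, 12, 107 and 18, with overlaps of 106, 10 and 7. Over probes above the floor on all 8 arrays rapamycin gave 1, with overlaps of 1 and 0. Rapamycin gave 9 genes with median centring, 7 with a trended robust variance and 10 with array weights. At an adjusted p under 0.01 JQ1 gave 28, the combination 117, the combination against rapamycin 0 (2339 at an unadjusted p under 0.05) and the overlap 26. With the header's names, on the non-normalized signals with an offset of 50, the counts were 3, 46, 367, 53 and 0 (619 at an unadjusted p under 0.05). The same signals with their arrays matched to the value table gave 648, 20, 1324, 0 and 656. The interaction stayed at 0 under both namings.

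Leaving out 1 array at a time, where the lone array of a group is assumed to vary like the other groups, gave 0 to 163 genes for JQ1, 0 to 4 for rapamycin, 0 to 555 for the combination, 0 to 0 against JQ1, 0 to 73 against rapamycin and 0 to 0 for the interaction. The overlaps ran from 0 to 119, 0 to 4 and 0 to 1.

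Values that changed sign were RUNX2 with no further background step (0.45 for JQ1, 0.41 for rapamycin) and, with the mean of a gene's probes under rapamycin, FKBP1A (-0.08) and RUNX2 (0.06). With no further background step the brightest probe was chosen anew, so those RUNX2 values may come from its second probe. The other sign changes came without 1 array and concern genes that were not called, given here with the range over the arrays left out. BRD3 in the combination ran from -0.22 (without combination 1) to 0.27 and was -0.15 without DMSO 1. MTOR ran from -0.24 (without rapamycin 1) to 0.34 with rapamycin, and was -0.19 without DMSO 2. With the combination MTOR ran from -0.23 (without combination 1) to 0.67, and was -0.02 without DMSO 2; with JQ1 it ran from -0.12 (without JQ1 1) to 0.87. FKBP1A with rapamycin ran from -0.16 (without rapamycin 2) to 0.23, and was -0.01 without DMSO 2. FOSL1 ran from -0.27 (without JQ1 1) to 0.49 with JQ1 and from -0.37 to 0.03 (without combination 2) with the combination. CCND1 with JQ1 ran from -0.79 to 0.11 (without JQ1 2). The list of ATF4 targets, combination against JQ1, had a median from 0 (without combination 1) to 0.50.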

Other observations

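The comparison of replicate sets in this part was chosen only after the data had been seen, and so were the genes named.

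The arrays numbered 2 differed from those numbered 1 in genes of glycolysis and the hypoxia response. With group and replicate number in 1 limma model, 1593 of 12759 genes differed between the sets, 1034 higher and 559 lower in set 2. Of 36 glycolysis and hypoxia genes, 26 were higher and 1 lower in set 2 (median 1.06, adjusted p = 3.46e-16; adjusted p = 0.142 with an estimated correlation). Examples from the list were PFKFB4 (log2 2.03, adjusted p = 0.00101), PGK1 (1.64, adjusted p = 0.00106) and BNIP3 (2.05, adjusted p = 0.00117). Outside the list, ANGPTL4 (3.88, adjusted p = 0.000815) and CA12 (2.13) were also higher in set 2. MYC targets were lower in set 2 (median -0.55, 19 of 37 lower and 1 higher, adjusted p = 8.87e-13; adjusted p = 0.142 with an estimated correlation), as were G1/S genes (median -0.33, 14 of 48 lower, adjusted p = 1.22e-09; adjusted p = 0.301 with an estimated correlation). Pentose phosphate and nucleotide synthesis genes (median -0.31, adjusted p = 0.0122) and heat shock and RNA handling genes (-0.27, adjusted p = 0.0214) were lower in set 2, and haematopoietic markers higher (0.44, 3 of 10 higher, adjusted p = 0.0461). With an estimated correlation their adjusted p were 0.301, 0.328 and 0.344. Under the header's names this same contrast is rapamycin treatment.

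Called members of 6 lists that were not themselves called for the combination against DMSO went both ways. In the MYC family 2 of 11 rose and 1 fell, with 3 and 2 adjusted over the list alone (adjusted p = 0.218; adjusted p = 0.421 with an estimated correlation). Of 16 P-TEFb and elongation genes 1 rose and 1 fell, with 2 and 2 adjusted over the list alone and the same 2 adjusted p. Of 39 interferon response genes 1 rose and 2 fell, with 3 and 6 adjusted over the list alone (adjusted p = 0.896; adjusted p = 0.909 with an estimated correlation). In insulin and growth factor signalling feedback 5 of 25 rose and 2 fell, with 6 and 3 adjusted over the list alone (adjusted p = 0.251; adjusted p = 0.59 with an estimated correlation). In the BCL2 family 2 of 21 rose and 2 fell, with 2 and 3 adjusted over the list alone (adjusted p = 0.499; adjusted p = 0.606 with an estimated correlation). In NF-kB targets and cytokines 3 of 28 rose and 3 fell, with 6 and 3 adjusted over the list alone (adjusted p = 0.251; adjusted p = 0.421 with an estimated correlation). Against DMSO, the insulin receptor substrate IRS1 fell (log2 -3.07, adjusted p = 0.0174) while IRS2 rose (2.88, adjusted p = 0.00726). The anti-apoptotic BCL2L1 fell (-1.68, adjusted p = 0.0184) and MCL1 rose (1.08, adjusted p = 0.0424). Of the cytokines, IL6 fell (-1.74) and IL11 rose (2.08). Against rapamycin, GDF15 fell (-2.58, adjusted p = 0.0326), as did LIF (-2.81) and IL6 (-2.63). ID1 rose with JQ1 against DMSO (1.49, adjusted p = 0.0317) and with the combination against rapamycin (1.71).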
